A study of Mus musculus with 2 samples.

How the data were processed

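H3K27ac ChIP-seq had been done on facial prominences of mouse embryos at 14.5 days, in 2 biological replicates of 1 group (pools of 24 and 34 embryos of both sexes). The analysis began from 4 deposited peak lists in the narrowPeak format on mm10 (GRCm38): one per replicate, one called on both libraries together, and one holding the peaks the authors marked as replicated. Per the file headers and the lists of files, the per-replicate lists derive from each replicate's alignments with a control. The peak caller, its cutoff and the rule behind the replicated list are not given in the sources used here.

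The fold enrichment is a ratio to control computed by the authors' peak caller. The significance is the −log10 p and −log10 q of the same caller, as deposited. The deposited display score of each peak was not used. The lists hold no read counts, so the depth of each library is unknown and no interval or floor that needs it was computed. Every peak had a −log10 p above 2, and the share with at least 5 was 62.9% in replicate 1, 55.8% in replicate 2 and 93.3% in the replicated list. The replicated list was checked against the others: all of its 52681 peaks were in the pooled list, it held all 40256 pooled peaks with an overlap of at least 50% of either peak in both replicates, and 12425 of its peaks (23.6%) had no such overlap in both.

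Genes came from GENCODE vM21 (21826 protein-coding genes with 58690 transcript starts; 141862 starts over all genes), and the sequence was the GRCm38 reference. A peak was a promoter peak when it lay within 1000 bp of a transcript start of any gene, and distal otherwise. A gene was marked when a peak lay within 1000 bp of any of its own starts. A distal peak was assigned to the protein-coding gene with the nearest start, within 100 kb. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, and samtools 1.23.1. Interval overlaps were checked against bedtools 2.31.1 and were equal.

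The gene lists, motifs, tests and the alternatives were fixed before the data were examined, except where a test is said to have been chosen later. There were 25 gene lists with 517 genes, of which 516 were found as protein-coding. The exception was Xist, a lincRNA, and Tbxt was found under the symbol T. A gene could stand in several lists, and the 516 genes gave 575 memberships. Each of the facial mesenchyme, cleft, signalling, bone and tooth lists shares members with others of these, so their results are not separate observations. The lists were facial mesenchyme regulators, orofacial cleft genes, signalling ligands and feedback genes, cartilage, bone, tooth, epithelium and periderm, skeletal muscle, neurons, olfactory and nasal epithelium, Schwann cell and melanocyte, endothelium and pericytes, erythroid, macrophage and other leukocyte, liver, heart, lung with gut, pancreas and kidney, germline and pluripotency, posterior limb and trunk regulators, the 4 Hox clusters, housekeeping, and X inactivation with Y-linked genes.

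With 1 group there was no comparison between groups and no test on samples. All tests were two-sided, except the one-sided binomial test of neuron promoters. They ran over genes, peaks or windows, which are not independent replicates, and describe these peak lists. Replicate overlap was the share of peaks overlapping the other list by at least 1 bp, beside 100 random placements on the same chromosome. Replicate agreement was Pearson's r of log2 fold enrichment and Spearman's rho, with the strongest overlapping peak of each replicate. Promoter marking of each list was tested against all other protein-coding genes with Fisher's exact test. The mean number of distal peaks per list was tested against 10000 random lists matched on decile of the sequence nearest to each gene. Distal peaks at most 10 kb apart were joined into domains, ranked by the sum of width times fold, and the first 30 were listed. Hox coverage was the covered share of the span from the first to the last gene of each cluster.

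Of 28 consensus motifs, each was counted on both strands in 500 bp centred on the summits of distal peaks and in 1 control window per peak. The control window had equal width, lay 5 to 50 kb away outside pooled peaks and fell in the same bin of 2% GC content; 97.0% of peaks had one. Shares were compared with Fisher's exact test, and intervals of the log2 odds ratio were 95% Woolf intervals. For the pair of CAGATG with TAATTR or YAATTA, 84 combinations of orientation and spacing from 0 to 20 bp were tested with exact binomial tests. Adjusted p values are Benjamini-Hochberg values within each family of 25 lists, 28 motifs or 84 spacings, with a threshold of 0.05. The replicate difference of a list was the median log2 ratio of promoter fold, less the median of all promoters, placed among 10000 random lists matched on mean fold.

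Genes were named by a rule. For each list, up to 4 members with the strongest promoter peak and up to 4 unmarked members in list order were named. The genes nearest to the first 30 domains were named, with values for the first 12. The 3 members with most distal peaks were named for cartilage, bone, facial mesenchyme and skeletal muscle. The 5 promoters with the largest ratio between replicates in each direction, among those in the upper 50% by mean fold, and every marked Hox gene were named.

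The alternatives were an overlap of 50% of both peaks, −log10 p of at least 5, the 50000 strongest peaks, promoter distances of 500 and 2500 bp, starts of protein-coding genes only, the outermost start only, the stronger peaks by fold, the pooled list, each replicate's list alone, random lists matched on promoter CpG content, assignment distances of 50 and 500 kb, no matching, joining distances of 5 and 20 kb, ranking by width or number of peaks, windows of 200 and 1000 bp, shuffled windows, −log10 p in place of fold, and another centring. Chosen after seeing the data were peaks that overlap a peak of each replicate and a threshold on 1 list of the overlap. Tested on simulated data, the promoter test recovered 98% of planted lists with 0.833% false calls (50 simulations of 21826 genes), the distal test 90% at 3 times the rate with 1.11% false calls (10 simulations), and the motif and spacing tests 100% with 0% false calls (10 simulations of 5000 windows each). The planted lists were strongly raised or lowered, and each motif was planted in 10% of windows of random sequence. The recovery and false calls therefore need not carry over to smaller differences, rarer motifs or genomic sequence. Peaks outside the numbered chromosomes, X and Y were left out of the gene and motif comparisons.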

Results

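H3K27ac, a histone acetylation found at active promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in the facial prominences of mouse embryos at 14.5 days. The facial prominences are the outgrowths of the embryonic head that form the jaws, palate and nose. All samples formed 1 group of 2 biological replicates, each a pool of embryos of both sexes: 24 embryos in replicate 1 and 34 in replicate 2. The values were peak lists, which hold no read counts, so the sequencing depth of each library is unknown and no counting interval is given. The labels state no question and name no second condition, so each comparison describes where acetylation lay in this tissue and how far the replicates agreed.

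The peak list of replicate 1 held 85959 peaks covering 44.4 Mb of GRCm38, and that of replicate 2 held 87781 peaks covering 41.0 Mb. The median fold enrichment over control was 3.79 in replicate 1 and 3.87 in replicate 2. A list called on both libraries together held 110598 peaks. The replicated list, a subset of it that the authors marked as replicated, held 52681 peaks with a median width of 618 bp and a median fold enrichment of 4.56. Of these, 40587 (77.0%) overlapped a peak of each replicate. The other 12094 (23.0%) did not, and their median fold enrichment was 3.63, against 5.22 for the peaks overlapping both. Unless stated otherwise, a peak below is a replicated peak and a fold is the authors' fold enrichment in the pooled libraries.

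The first comparison asked how far the peaks of the 2 pools coincided. Of the replicate 1 peaks, 55.8% overlapped a replicate 2 peak, and of the replicate 2 peaks 58.2% overlapped a replicate 1 peak. Randomly placed peaks of the same widths overlapped in 3.41% and 3.04% of cases (means of 100 placements). The share fell with peak strength, from 99.9% of the 10000 strongest replicate 1 peaks to 31.3% of the weakest class. When an overlap had to cover 50% of both peaks, 31.4% of replicate 1 peaks were shared.

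**Figure D1:**
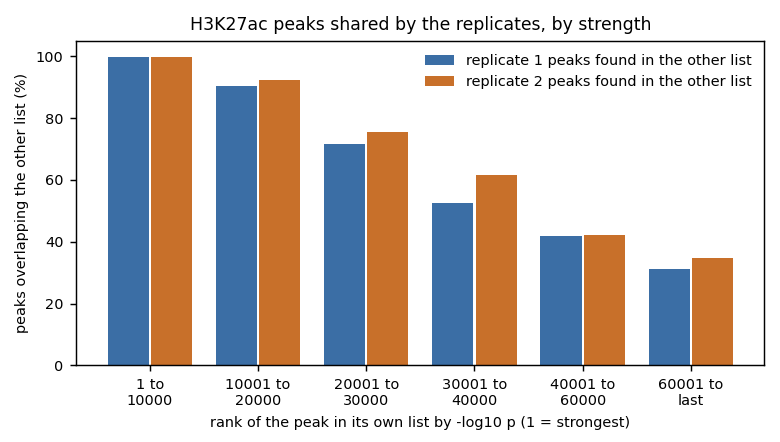
Share of peaks (%, vertical axis, from 0) that overlap a peak of the other replicate, by rank of the peak in its own list by −log10 p (horizontal axis, 1 = strongest), with 1 bar per replicate and rank class. The bars stand at 99.9% for both replicates in the strongest class and at 31.3% and 34.9% in the weakest.

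Fold enrichment at the 40587 peaks found in both replicates correlated with a Pearson r of 0.806 on the log2 scale and a Spearman rho of 0.672. These are correlations across peaks, which are not independent replicates, so no p is given. The replicates lay within 2-fold of each other at 93.6% of these peaks. At promoter peaks r was 0.837 and 90.7% lay within 2-fold (SD of the log2 ratio 0.56), and at distal peaks r was 0.618 and 95.5% lay within 2-fold (SD 0.50). The median log2 ratio of replicate 2 to replicate 1 was −0.08 with an SD of 0.53 over peaks.

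The next comparison asked how much of the acetylation lay at promoters. Of the 52681 peaks, 18481 (35.1%) lay within 1000 bp of an annotated transcript start, against 8.50% of randomly placed peaks. Promoter peaks had a median fold of 7.0 and the 34200 distal peaks a median fold of 4.14. A promoter peak was found at 11602 of 21826 protein-coding genes (53.2%). The lincRNA Xist, which coats the inactive X chromosome, had a promoter fold of 9.53 (8.23 in replicate 1 and 7.19 in replicate 2), and the Y-linked Ddx3y and Uty each had 10.7.

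Several lists of genes that build the face were acetylated at their promoters more often than other genes. Of 51 transcription factors of the facial mesenchyme, the connective tissue of the prominences, 48 (94.1%) had a promoter peak, against 53.1% of all other protein-coding genes (Fisher's exact test, adjusted p = 5.56e-09). Orofacial cleft genes were marked in 34 of 40 cases (85%, exact adjusted p = 0.000253) and signalling ligands and feedback genes in 30 of 38 (78.9%, exact adjusted p = 0.00464). Olfactory and nasal epithelium genes were marked in 16 of 20 cases (80.0%, exact adjusted p = 0.0435), and all 28 housekeeping genes were marked (exact adjusted p = 4.96e-07). The cleft, signalling and olfactory calls ended against random lists matched on promoter CpG content, as given below.

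In the facial mesenchyme list the strongest promoter peaks lay at Pbx1, Alx4, Meis1 and Prrx1, all homeodomain factors. Pbx1 (chromosome 1, 168119364 to 168432270) had a fold of 49.1, with 29.5 in replicate 1 and 42.7 in replicate 2. Alx4, a regulator of the frontonasal skeleton, had a fold of 45.8 (31.2 and 48.1 in the replicates, n = 2). Meis1 had 41.2 (33.1 and 35.4, n = 2), and Prrx1 had 39.2 (45.3 and 41.2, n = 2) over a peak of 11114 bp at chromosome 1, 163304540 to 163315653. The 3 unmarked members were Dlx3, Hand1 and Tbx22. The median promoter fold of the marked members was 14.4, against 10.9 for all marked protein-coding genes.

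Among the cleft genes the strongest promoter peaks lay at the Hedgehog receptor Ptch1 (fold 48.4; 37.6 and 38.3 in the replicates), Alx4, Zfhx4 (43.3) and the FGF antagonist Spry2 (43.1; 43.8 and 24.9 in the replicates). Tbx22, Wnt9b, Wnt3 and Foxe1 had no promoter peak. Among the signalling genes the Wnt feedback gene Axin2 had a fold of 49.0 (37.9 and 43.1 in the replicates), and the Hedgehog transcription factor Gli3 had 41.8. The ligands Shh and Fgf8 and the antagonists Hhip and Grem1 had no promoter peak. In the olfactory list the strongest were Ebf1 (24.7), Gng8 (17.4), Six1 (15.2) and Dlx5 (13.1), while the neurogenic factors Ascl1, Neurog1 and Neurod1 and the odorant neuron marker Omp were unmarked. The strongest housekeeping promoters were those of Actb (71.7; 66.3 and 48.2 in the replicates), Ywhaz (57.3), Ubb (43.4) and Vcp (38.8).

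Genes of the skeletal, dental and epithelial cells of the face were marked at frequencies that did not pass the test against other genes. The counts were 14 of 23 for cartilage (exact adjusted p = 0.607), 13 of 19 for bone (exact adjusted p = 0.343), 12 of 22 for tooth (exact adjusted p = 1) and 22 of 36 for epithelium and periderm (exact adjusted p = 0.505). The chondrocyte regulator Sox9 had a promoter fold of 25.3, with 19.0 in replicate 1 and 17.2 in replicate 2. The cartilage collagens Col2a1, Col9a3 and Col11a1 had 11.7, 11.3 and 10.9, whereas Acan, Matn1, Comp and Snorc were unmarked. The bone collagen Col1a1 had a promoter fold of 25.5 and lay under the widest peak of the list, 19480 bp at chromosome 11, 94932297 to 94951776. Pth1r (22.4), Satb2 (21.5) and Col1a2 (20.9) followed, and the late osteoblast and osteocyte genes Spp1, Bglap, Ibsp and Dmp1 were unmarked. Ibsp had a promoter peak in replicate 2 alone and Dmp1 in replicate 1 alone, and both were marked in the pooled list.

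In the tooth list Runx2 (18.6), Lhx8 (17.5), Bmp4 (15.4) and Msx1 (9.61) were strongest, and Shh, Fgf4, Fgf3 and Wnt10a were unmarked. In the epithelium list Elf3 (9.77), Esrp1 (9.53), Grhl2 (9.26) and Epcam (7.39) were strongest, and the keratin genes Krt15, Krt8, Krt18 and Krt19 were unmarked. The median promoter fold was 5.46 for epithelium, 8.44 for cartilage and 15.1 for bone.

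Muscle, nerve, glial and vessel genes did not pass the test either. The counts were 22 of 34 for skeletal muscle (exact adjusted p = 0.336), 9 of 26 for neurons (exact adjusted p = 0.126), 9 of 18 for Schwann cell and melanocyte (exact adjusted p = 0.851) and 18 of 28 for endothelium and pericytes (exact adjusted p = 0.343). In muscle, the sarcomere gene Mylpf (11.4, under a peak shared with Tbc1d10b), Tbx1 (8.08), Pax7 (6.57) and Tnnt1 (6.39) were strongest, and Myf6, Tcf21, Acta1 and Actc1 were unmarked. In neurons Elavl4 (6.04), Tubb3 (4.99), Gap43 (4.93) and Nefl (4.78) were strongest, and Snap25, Syt1, Nefm and Nefh were unmarked. Pmel (24.6) and Mpz (15.4) led the Schwann cell and melanocyte list under peaks shared with the promoters of Cdk2 and Sdhc, followed by Erbb3 (12.03). In the vessel list Fli1 (16.3), Ets1 (13.1), Pdgfrb (12.4) and Eng (11.6) were strongest, and Flt1, Flt4, Tie1 and Sox17 were unmarked. Of the 4 protein-coding genes of the X inactivation and Y-linked list, 3 were marked (exact adjusted p = 0.683).

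The position of several of these lists depended on the peak set and on the background. Skeletal muscle was marked less often than other genes among the stronger peaks (difference −20.7 percentage points, exact adjusted p = 0.0251) and more often against lists matched on promoter CpG content (64.7% against 38.2%, permutation adjusted p = 0.00187) and in the peaks of replicate 1 alone (difference 23.3 percentage points, exact adjusted p = 0.0137); over all alternatives its adjusted p ran from 0.00187 to 0.702. Against matched lists bone was marked more often (68.4% against 32.3%, permutation adjusted p = 0.003, range over the alternatives 0.003 to 1) and neurons less often (34.6% against 62.9%, adjusted p = 0.00545, range 0.00177 to 0.917). In the peaks of replicate 2 alone epithelium genes were marked more often (exact adjusted p = 0.0104, range 0.000378 to 0.734) and neurons less often (exact adjusted p = 0.00177).

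Genes of blood, of other organs and of more posterior body regions were marked less often than other genes, although the erythroid, macrophage, liver and heart calls ended against lists matched on promoter CpG content, as given below. The counts were 4 of 19 for erythroid (exact adjusted p = 0.0122), 5 of 24 for macrophage and other leukocyte (exact adjusted p = 0.00464), 2 of 20 for liver (exact adjusted p = 0.000538) and 4 of 20 for heart (exact adjusted p = 0.00777). They were 1 of 26 for lung, gut, pancreas and kidney (exact adjusted p = 1.29e-06), 2 of 20 for germline and pluripotency (exact adjusted p = 0.000538) and 5 of 20 for posterior limb and trunk regulators (exact adjusted p = 0.0274). The erythroid master factor Gata1 and the globin genes Hba-a1, Hba-a2 and Hbb-bt were unmarked, while Ank1 had a fold of 6.45 and Klf1 of 5.45. The leukocyte genes Ptprc, Csf1r, Cx3cr1 and Adgre1 were unmarked, and Cd68 had a fold of 4.88. Alb, Afp, Apoa1 and Apoa2 in liver and Nkx2-5, Gata4, Gata5 and Gata6 in heart were unmarked.

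Several marked members of these lists lay under the promoter peak of a neighbour. The liver genes Apoh (7.63) and Trf (4.47) shared their peaks with Prkca and Gm20425, and the heart genes Myl3 (22.4) and Myl4 (22.4) with Pth1r and Cdc27. Foxa1 (4.54) was the single marked gene of the lung, gut, pancreas and kidney list, in which Nkx2-1, Sftpc, Sftpb and Scgb1a1 were unmarked. Dazl (8.25) and Tdgf1 (4.54) were marked in the germline list, and Nanog, Pou5f1, Zfp42 and Dppa3 were not. In the posterior list Gdf11 (14.3) was strongest and Tbx5, Tbxt, Uncx and Pax1 were unmarked.

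Promoter CpG content was related to several of these calls. Against random lists matched on it, the calls ended for the cleft, signalling, olfactory, erythroid, macrophage, liver and heart lists, whose adjusted p reached 0.0583, 0.632, 0.561, 0.697, 1, 0.214 and 0.0923. Over all alternatives the adjusted p ran from 4.66e-05 to 0.0583 for cleft, from 0.000228 to 0.632 for signalling, from 0.0102 to 0.895 for olfactory, from 0.00133 to 0.697 for erythroid, from 0.00042 to 1 for macrophage, from 4.66e-05 to 0.214 for liver and from 0.01 to 0.0923 for heart. The facial mesenchyme list stood at 94.1% against 70.8% in matched lists (permutation adjusted p = 0.001, which rests on the smallest p that 10000 random lists can give; range over the alternatives 1.15e-11 to 0.001).

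**Figure D2:**
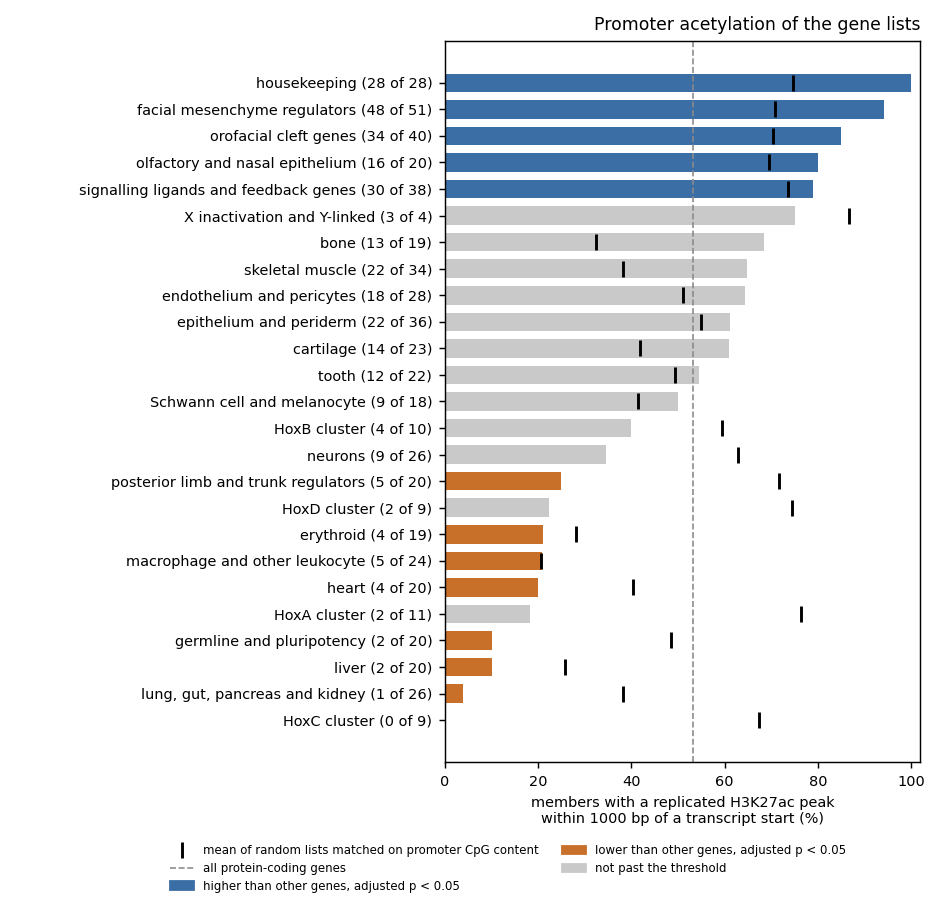
Share of the members of each gene list with a peak within 1000 bp of a transcript start (%, horizontal axis, from 0), with the counts beside the list names on the vertical axis. The dashed line marks all protein-coding genes (53.2%), the black ticks mark the mean of random lists matched on promoter CpG content, and the colours mark lists past the threshold in the exact test; facial mesenchyme stands at 94.1% and HoxC at 0%.

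Distal peaks were then counted around the same lists, and 4 of the 25 passed. A facial mesenchyme gene was the nearest gene, within 100 kb, of 6.35 ± 4.71 distal peaks (mean ± SD over 51 genes), against 2.36 in random lists matched on the length of sequence nearest to each gene (permutation adjusted p = 0.005). Cleft genes had 5.85 ± 6.09 against 2.44 (40 genes, permutation adjusted p = 0.005), signalling genes 5.26 ± 4.57 against 2.68 (38 genes, permutation adjusted p = 0.0412) and bone genes 5.16 ± 6.11 against 1.81 (19 genes, permutation adjusted p = 0.04). In the peaks of replicate 2 alone the excess over matched lists rose from 4.00 to 9.03 for facial mesenchyme, from 3.41 to 7.002 for cleft, from 2.58 to 5.08 for signalling and from 3.35 to 6.11 for bone, and in those of replicate 1 alone to 7.33, 5.67, 4.17 and 6.97. The lists of 1 replicate held more distal peaks: 61878 in replicate 2 and 59343 in replicate 1 had a control window, against 33158 replicated peaks. Counts of peaks grow with the list, so the larger excess does not show a stronger enrichment. Each of the facial mesenchyme, cleft, signalling and bone lists passed in either replicate, where 6 and 5 lists passed in all. Among the facial mesenchyme genes Twist2 had 18 distal peaks, and Prrx1 and Pbx1 had 16 each. In bone, the osteoblast master factor Runx2 had 22, Col1a2 14 and Sparc 12. In cartilage, which did not pass the test (3.30 against 1.59, permutation adjusted p = 0.138), Sox5 had 18, Col2a1 10 and Sox6 8.

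Olfactory genes had 2.45 against 2.19 (permutation adjusted p = 0.878) and housekeeping genes 0.642 more than their matched lists (0.251), so 2 of the 5 lists marked more often at promoters did not pass here. The other 18 lists did not pass either. Epithelium genes had 2.72 against 1.28 (permutation adjusted p = 0.0867), endothelium 3.71 against 1.83 (0.104), tooth 3.55 against 1.94 (0.243) and skeletal muscle 1.18 against 1.43 (0.878), in which Tbx1 and Pitx2 had 5 each and Des 3. Neurons had 0.615 against 2.23 (permutation adjusted p = 0.057). The signalling call ended with the stronger peaks alone (permutation adjusted p = 0.119) and with peaks overlapping both replicates (0.075). Over the alternatives its adjusted p ran from 0.00125 to 0.119.

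The strongest stretches of distal acetylation were then listed by joining distal peaks at most 10 kb apart, which gave 17072 domains. They were ranked by the sum of peak width times fold. The first spanned 96.4 kb on chromosome 1 (161998788 to 162095231) with 21 peaks and a highest fold of 25.9, overlapped Dnm3, and was nearest to a transcript start of 4930558K02Rik. The fifth, also in Dnm3, spanned 107.3 kb with 30 peaks. The second spanned 132 kb on chromosome 6 (50914437 to 51046006) with 44 peaks and a highest fold of 17.0, nearest to Npvf at 325783 bp. The ninth lay on the same chromosome (51102938 to 51174606), held 19 peaks and was nearest to Nfe2l3. The third (chromosome 2, 30684694 to 30724869, nearest to 1700001O22Rik) reached a fold of 62.0, and the fourth (chromosome 12, 79878833 to 80024125) held 38 peaks nearest to Zfp36l1. Domains took the nearest gene at any distance, without the 100 kb limit set for single distal peaks. The fourth lay 161514.5 bp from Zfp36l1 and the ninth 293897.5 bp from Nfe2l3.

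The next ranks were taken by domains nearest to Tex44 (38.1 kb, highest fold 61.3), Irf2bp2 (15.7 kb, 39.0), Lrrc74a (73.9 kb, 32.9), Chd2 (12.6 kb, 63.3), Ncor2 (83.7 kb, 36.0) and Tgoln1 (108 kb, 22.6, overlapping the Wnt effector gene Tcf7l1). The remaining 18 were nearest to Nxn, Morn1, Btd, Ppm1h, Acot11, Usp29, Nfix, Col1a1, Sorl1, Twist1, Atp23, Ccr7, Cstad, Haao, Ddc, Mrpl23, Sept9 and Rxra. Col1a1 and Twist1 were the 2 nearest genes found in any gene list. No test was run. Of the 30 nearest genes, 13 to 28 stayed among the first 30 under the alternatives, with 13 when domains were ranked by the number of peaks. Of the first 12, 7 to 12 were kept. The first rank went to Npvf by total width, Nxn by number of peaks, 1700001O22Rik when joining at 5 kb and Zfp36l1 in replicate 1 alone.

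The Hox clusters, whose genes give cells their position along the body axis, were acetylated in part. Peaks covered 13.0% of HoxA, 5.72% of HoxB and 5.21% of HoxD, and 0% of HoxC, against 2.83% of the spans of all other protein-coding genes. A Hox span takes in a whole cluster of genes and each other span a single gene, so these shares are not of like regions. Promoter peaks lay at Hoxa2 (fold 10.1), Hoxa4 (3.404), Hoxb2 (6.11), Hoxb4 (4.31), Hoxb3 (4.09), Hoxb7 (3.404), Hoxd3 (4.31) and Hoxd8 (3.95), while Hoxa1, Hoxa3, Hoxb1, Hoxd1 and Hoxd4 were among the unmarked genes. The peak at Hoxa2, the Hox gene that patterns the second pharyngeal arch, spanned 6312 bp at chromosome 6, 52162778 to 52169089. None of the 9 HoxC genes was marked, fewer than among other genes (exact adjusted p = 0.00387), and the adjusted p was 0.0755 in the peaks of replicate 1 alone (range over the alternatives 0.001 to 0.0755). HoxA was marked in 2 of 11 genes (exact adjusted p = 0.0541), HoxB in 4 of 10 (exact adjusted p = 0.607) and HoxD in 2 of 9 (exact adjusted p = 0.145). Against random lists matched on promoter CpG content, HoxA was marked less often (18.2% against 76.3%, permutation adjusted p = 0.001, which rests on the smallest p that the lists can give; range over the alternatives 0.001 to 0.302), as was HoxD (22.2% against 74.4%, permutation adjusted p = 0.003; range 0.003 to 0.191).

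The Hox coverage came mainly from replicate 1. Its peaks covered 16.6% of HoxA, 11.9% of HoxB and 7.98% of HoxD, and those of replicate 2 covered 1.51%, 0.441% and 1.501%. Hoxa2 had a fold of 8.96 in replicate 1 and 4.27 in replicate 2, Hoxb2 had 8.96 and 3.99 and Hoxd3 6.202 and 3.59, whereas Hoxd8 was higher in replicate 2 (3.23 and 3.99). Hoxa4, Hoxb3 and Hoxb4 had a peak in replicate 1 alone, and Hoxb7 in replicate 2 alone.

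**Figure D3:**
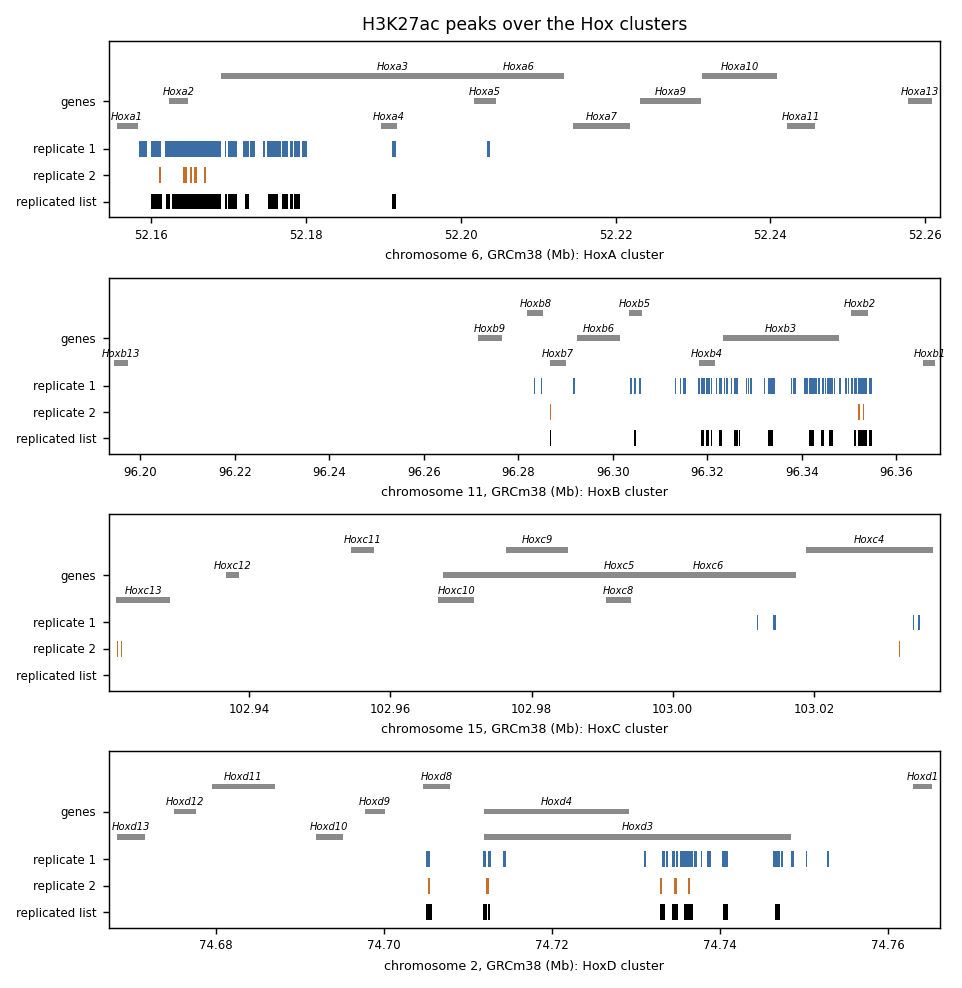
Position of the peaks over the 4 Hox clusters (horizontal axis, Mb of GRCm38), with the genes in grey and peaks of replicate 1 in blue, of replicate 2 in orange and of the replicated list in black. Blue peaks cover 16.6% of HoxA and orange peaks 1.51%.

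The replicates were next compared at promoters, list by list, as the log2 ratio of fold in replicate 2 to replicate 1, less the median of all 10845 promoters compared (−0.29). Of the 16 lists with at least 4 promoters, 6 lay outside the middle 95% of random lists of like fold, all toward replicate 2 after this centring. The medians were 0.75 for tooth (11 genes, SD over genes 0.69), 0.50 for bone (13, 0.50), 0.47 for facial mesenchyme (48, 0.64), 0.43 for epithelium (18, 0.61), 0.37 for signalling (29, 0.45) and 0.32 for cleft genes (31, 0.60). The 6 lists share members, such as Msx1 in facial mesenchyme, cleft and tooth, so they are not 6 separate observations. Of the 48 facial mesenchyme promoters 35 lay above the median ratio of all promoters, and the median of no random list of the 10000 exceeded theirs (percentile 100). Housekeeping genes had a median of 0.07 (27 genes, percentile 76.3). With 1 library per pool, these values describe these libraries, and no p is given.

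Among the stronger promoters the ratio was highest at Sostdc1, an antagonist of BMP and Wnt signals in teeth (fold 5.09 in replicate 1 and 16.6 in replicate 2, log2 ratio 1.71), and at the neural crest factor Tfap2b (6.57 and 21.2, log2 ratio 1.69). Gm20388 with Usp10, Slc2a12 and Mfap2 followed with log2 ratios of 1.59, 1.58 and 1.45. The ratio was lowest at Rfx5, an activator of MHC class II genes (25.03 in replicate 1 and 5.22 in replicate 2, log2 ratio −2.26), followed by Ssu72 (−1.96), Uhrf1bp1l (−1.94), Isy1 (−1.87) and Cdk11b (−1.85).

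**Figure D4:**
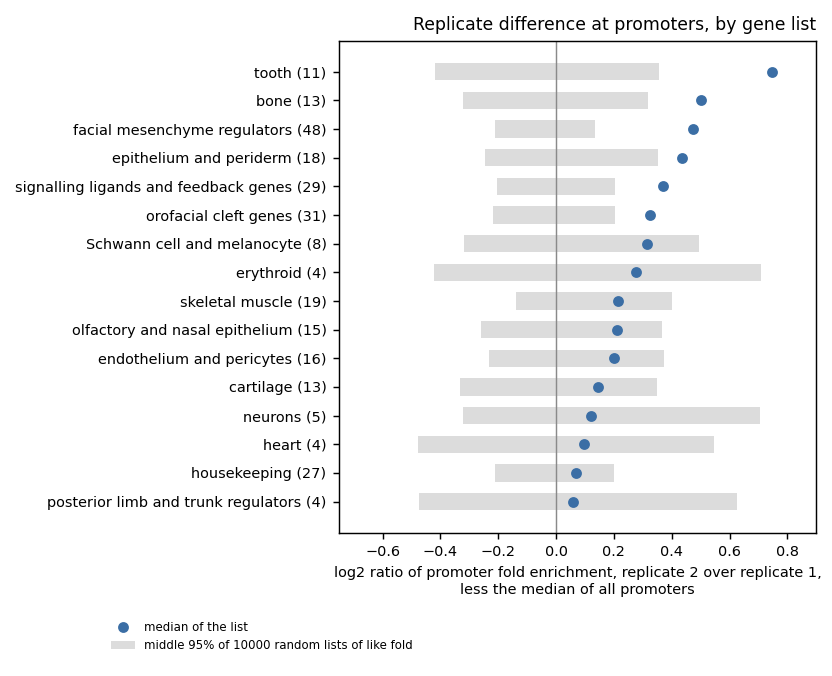
Median log2 ratio of promoter fold enrichment, replicate 2 over replicate 1, less the median of all promoters (horizontal axis), for each gene list (vertical axis, number of promoters in brackets). Blue points are list medians and grey bars the middle 95% of 10000 random lists of like fold; facial mesenchyme lies at 0.47 and housekeeping at 0.07.

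Motifs of known families of transcription factors were counted in 500 bp around the summits of distal peaks and in nearby windows of equal GC content (33158 of each). Of 28 motifs, 17 were more frequent in peaks and 3 less frequent (Fisher's exact test). The E-box CAGCTG, bound by bHLH factors, was found in 31.5% of peaks and 25.05% of control windows (odds ratio 1.37, exact adjusted p = 3.1e-74). The motif of MEF2, a muscle and neural crest factor, was found in 1.31% against 0.636% (2.08, exact adjusted p = 1.85e-18). FOX stood at 7.96% against 5.98% (1.36), TFAP2 at 14.8% against 11.4% (1.34), SOX at 55.3% against 51.0% (1.19) and TEAD at 29.1% against 26.1% (1.17). The SOX dimer, an arrangement used by chondrocyte SOX factors, was rare and stood at 0.0633% against 0.0241% (2.63, exact adjusted p = 0.0355). Its call ended in the stronger 50% of peaks (log2 odds ratio 0.17, exact adjusted p = 1), in 200 bp windows (0.943) and with peaks overlapping both replicates (0.265), and its adjusted p ran from 3.92e-07 to 1 over the alternatives.

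The other motifs more frequent in peaks were NRF1, ETS, HOX-PBX, KLF or SP, p53 or p63, the glucocorticoid receptor, LEF or TCF, RUNX, homeodomain TAATTA and the E-box CAGATG, with odds ratios from 1.05 for CAGATG to 2.00 for NRF1. NFY (0.805), PITX or OTX (0.818) and GATA (0.867) were less frequent. Repeated sequence was neither masked nor matched between peaks and control windows, and its part in these odds was not tested. In 200 bp windows 10 of the 17 motifs no longer passed, among them TEAD (log2 odds ratio 0.05, exact adjusted p = 0.254, range over the alternatives 1.35e-128 to 0.254), RUNX, TAATTA, NRF1, HOX-PBX and p53 or p63. All 17 still passed in 1000 bp windows, 14 in the stronger 50% of peaks, 12 with peaks overlapping both replicates, 15 and 14 in the peaks of 1 replicate alone and 13 against shuffled windows. NRF1 and RUNX passed in the peaks of neither replicate alone. Their log2 odds ratios there were 0.42 and 0.44 for NRF1, against 1.00, and 0.044 and 0.043 for RUNX, against 0.098. The odds of ETS and KLF or SP turned below 1 in 200 bp windows and against shuffled windows, those of CAGATG in 200 bp windows and those of TAATTA against shuffled windows. CTCF, with a log2 odds ratio of −0.07 (exact adjusted p = 0.763), lay at −1.51 in 200 bp windows and at 0.55 in 1000 bp windows.

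**Figure D5:**
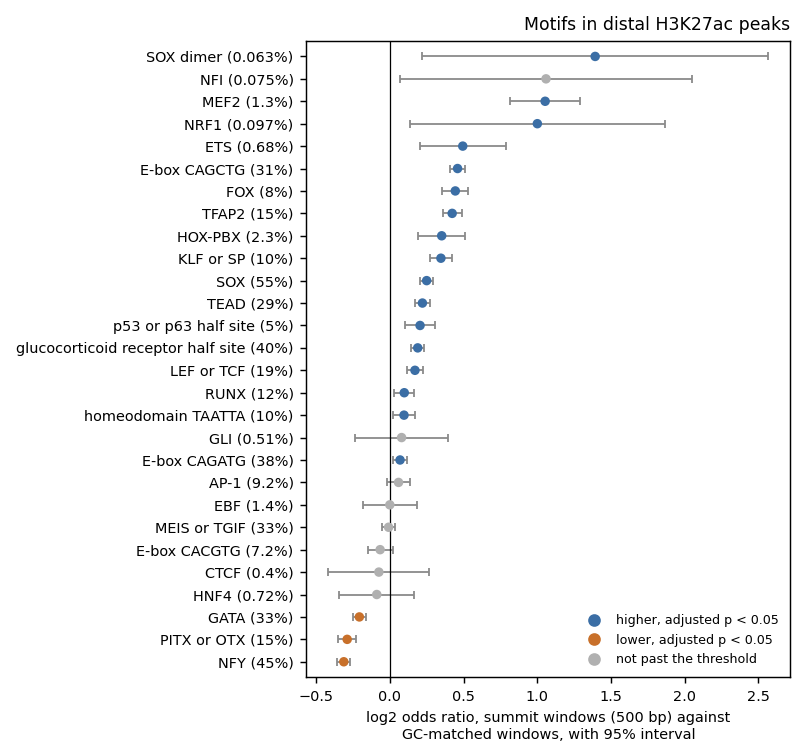
Log2 odds ratio (horizontal axis) of each motif in 500 bp on the summits of distal peaks against GC-matched windows, with its 95% interval as bars; the share of peaks with the motif stands in brackets beside its name on the vertical axis. Blue points are higher and orange points lower past the threshold; the CAGCTG point stands at 0.46 and NFY at −0.31.

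The last comparison asked whether the E-box CAGATG and a homeodomain site kept a fixed distance, as bHLH and homeodomain factors are both in the facial mesenchyme list. In 500 bp windows none of 84 combinations of spacing and orientation was in excess by an exact binomial test, with 5 at an unadjusted p under 0.05 and a smallest adjusted p of 0.328. In 1000 bp windows 2 were: TAATTR, then CAGATG after 4 bp, in 49 peaks against 6 control windows (exact adjusted p = 1.53e-07), and YAATTA, then CAGATG after 4 bp, in 38 against 5 (exact adjusted p = 1.05e-05). The 2 combinations overlap, as TAATTA fits both TAATTR and YAATTA, and together they took in 64 peaks against 8 control windows. The same 2 passed in 500 bp windows on the peaks of replicate 2 alone, with 30 against 8 and 36 against 6. They also passed on those of replicate 1 alone, with 31 against 8 and 28 against 7. The lists of the replicates shared many peaks, so these are not separate observations. None passed in 200 bp windows, nor in 500 bp windows on peaks overlapping a peak of each replicate.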

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

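Of the tests reported here, those of neuron promoters, of the epithelium list and of the motifs by distance from the summit were chosen after the results were seen. The Hox coverage, CpG and width tests were written down before they were run, but after the patterns they address were seen.

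The pooled list held 17868 peaks with a −log10 p of at least 5 that were not in the replicated list and entered none of the main comparisons. The replicated list held 7 peaks outside the numbered chromosomes, X and Y, which were in no gene or motif comparison.

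The Hox clusters were covered far more by the peaks of replicate 1 than by those of replicate 2, with a log2 ratio of 3.37 over HoxA, HoxB and HoxD. Replicate 1 held 85959 peaks (44.4 Mb) and replicate 2 held 87781 (41.0 Mb), so replicate 1 had fewer peaks but covered more sequence. It also marked more coding genes (12259 against 11598). These values alone do not decide whether more was called everywhere in replicate 1. Such an excess would have raised other windows as well. The Hox ratio lay at percentile 100 of triples of 100 kb windows of similar coverage and fold. The 3 clusters were chosen after their coverage was seen. HoxC, covered at 0.814% in replicate 1 and 0.479% in replicate 2, was left out. Taken singly, HoxA lay at percentile 100, HoxB at 99.8 and HoxD at 99.6. The ratio over the 3 clusters was 3.94 with the 50000 strongest peaks of each list. A pool of replicate 1 that held more neurons or Hox-expressing tissue is a candidate explanation. Neuron promoters with a peak in 1 replicate alone were in replicate 1 in 7 of 7 cases, but 70.4% of such promoters of all genes were too. The one-sided exact binomial p of 0.0858 is the smallest that 7 promoters can give here, so the test could not pass and this remains open. Elavl4, the strongest neuron promoter, had a fold of 6.202 in replicate 1 and 5.19 in replicate 2. The 5 neuron promoters compared between the replicates had a median centred log2 ratio, replicate 2 over replicate 1, of 0.12. This lay at percentile 45.0 of random lists of like fold, with 4 of the 5 above the median of all promoters. Only promoters with a peak in both replicates entered this ratio, which left out the 7 neuron promoters with a peak in replicate 1 alone. The 5 promoters compared therefore decide nothing on this explanation. The labels name no biological difference between the pools, so apart from tissue make-up no biological explanation was tested.

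Facial mesenchyme promoters were higher in replicate 2 relative to all promoters, with a median centred log2 ratio of 0.47. Random lists matched on promoter CpG content and fold placed this at percentile 100, and lists matched on peak width and fold at percentile 99.96, so neither property accounted for it in full. A larger share of mesenchyme cells in the pool of replicate 2 was predicted to lower the epithelium list. That list stood at percentile 99.37 in the same direction with a median of 0.43. The value goes against mesenchyme cells gained at the cost of epithelium alone, and it had been seen when the prediction was written. The ratio is centred on all promoters, so both lists could rise together. A larger mesenchyme share with a lower share in replicate 2 of some tissue outside both lists may remain and was not tested. The labels name no biological difference between the pools, so apart from tissue make-up no biological explanation was tested.

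Several motif results turned with the width of the window, among them CTCF, which lay at a log2 odds ratio of −1.51 in 200 bp and 0.55 in 1000 bp. Peaks and random windows held on average 49.2% and 49.1% GC in 200 bp, and 46.8% and 46.7% in 1000 bp. A difference in GC content of the random windows was thus small, and it would not produce a contrast within the same peaks. Of these peaks, 13 had the motif at the summit alone and 46 in the flank alone (exact McNemar p = 1.92e-05). This contrast follows from the shares in peaks by window width and tests nothing further. A nucleosome on the summit with free sites beside it may remain: the CTCF log2 odds ratio of 1.23 in 100 bp windows 300 bp from the summit follows from the values by window width and tests nothing further, no positions of nucleosomes were measured, and motifs went both ways, with CAGCTG, TEAD, KLF or SP, CAGATG, RUNX and MEF2 among those lower at the summit (CAGCTG 0.28 against 0.56 at 300 bp) and SOX, FOX and TFAP2 among those higher there (SOX 0.20 against 0.06). These differences between summit and flank were not tested, and MEF2 at the summit rested on 44 peak windows and 25 random windows. More sequence searched in wider windows also remains open for the CAGATG and homeodomain pair 4 bp apart, which was found at 4 sites in peaks and 1 in random windows within 100 bp of the summit and at 16 and 2 sites at 250 to 350 bp (two-sided Fisher's exact p = 0.539). Over all 84 spacings the ratio of sites in peaks to sites in random windows was 0.962 within 100 bp. It was 1.53 at 250 to 350 bp (two-sided Fisher's exact p = 0.0117). These sites were placed by their first base, and those of the pair 4 bp apart by their centre. The comparison over all spacings takes in other spacings, restates the values by window width and decides nothing for this pair.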

How the results depend on the processing

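The alternatives using peaks that overlap a peak of each replicate, and a threshold on 1 list of the overlap, were chosen after seeing the data; the others were planned. Among the single lists, motifs and clusters tried under alternatives, those named here changed. Counting each result under each alternative, a result came to pass the threshold without a change of direction in 39 cases, and a motif ceased to pass it in 21 cases. In the other cases results past the threshold kept their direction and side. The lists and motifs that did not pass were of the opposite sign in 16 of 120 alternatives of promoter marking, 10 of 168 of distal peaks and 17 of 56 of motifs, among them cartilage (7.72 to −3.66 percentage points) and epithelium (7.97 to −8.26) in promoter marking among the stronger peaks. For the changes listed, the cause was not tested beyond what each setting implies. The depth of the libraries is unknown.

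The share of replicate 1 peaks found in replicate 2 was 31.4% with an overlap of 50% of both peaks, 60.3% with the 50000 strongest peaks and 69.5% with −log10 p of at least 5 in 1 list. The reverse share was 30.8%, 64.5% and 75.7%, and 66.8% with the threshold in both lists. The correlation was 0.618 at distal peaks. The promoter share of peaks was 32.01% at 500 bp, 42.4% at 2500 bp, 28.3% with protein-coding genes, 36.4% with −log10 p of at least 5, 24.5% with pooled peaks, 39.4% with peaks overlapping both replicates and 27.8% to 29.2% with 1 replicate left out. The share of coding genes marked was 58.6% with pooled peaks, 50.1% with peaks overlapping both replicates and 53.1% to 56.2% with 1 replicate left out.

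Promoter marking is given as the difference from other genes in percentage points. Pooled peaks gave 8 lists marked more often, and left macrophage at −21.2 (exact adjusted p = 0.0547, range 0.00042 to 1). Against lists matched on CpG content the differences were 14.7 for cleft, 5.33 for signalling, 10.5 for olfactory, −6.98 for erythroid, 0.218 (reversed) for macrophage, −15.7 for liver and −20.4 for heart. Olfactory genes stood at 17.5 at 500 bp, 4.69 with the outermost start, 17.9 among the stronger peaks, 24.96 with peaks overlapping both replicates and 21.9 to 23.9 with 1 replicate left out. With 1 replicate left out heart stood at −31.2 to −23.2 and HoxC at −42.0 to −34.0. Skeletal muscle reversed to −20.7 among the stronger peaks.

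With 1 replicate left out, the excess of distal peaks over matched lists was 7.33 to 9.03 for facial mesenchyme, 5.67 to 7.002 for cleft, 4.17 to 5.08 for signalling and 6.11 to 6.97 for bone. The lists of 1 replicate held more distal peaks than the replicated list, which raises such counts. The excess of signalling genes was 0.899 among the stronger peaks and 1.72 with peaks overlapping both replicates. Of the 30 nearest genes of the domains, 17 were kept when joining at 5 kb, 17 at 20 kb, 15 by total width, 13 by number of peaks and 18 to 23 with 1 replicate left out. With 1 replicate left out HoxA was covered at 1.51% to 16.6% and HoxC at 0.479% to 0.814%.

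In 200 bp windows 12 motifs passed, 7 of them higher. There the log2 odds ratio turned to −0.023 for CAGATG, −0.17 for AP-1, −0.038 for ETS and −0.029 for KLF or SP. Against shuffled windows it turned to −0.69 for TAATTA, −0.88 for ETS, −0.97 for KLF or SP, 2.25 for CTCF, 1.17 for HNF4, 1.03 for EBF and 0.95 for MEIS or TGIF. CTCF turned to 0.55 in 1000 bp windows, and MEIS or TGIF stood at 0.034 to 0.041 with 1 replicate left out. The spacings that passed were 2 in 1000 bp windows and 2 with either replicate left out, and these 2 overlap, as TAATTA fits both. None passed in 200 bp windows or with peaks overlapping both replicates.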

Other observations

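The tests of the lists with pooled peaks were planned, whereas the comparisons of peak widths and of promoters marked in 1 replicate, and the genes named in this part, were chosen after the results were seen.

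Peaks found in the pooled list alone added promoters to 20 of the 25 lists, and the gains of the lists were not compared by a test. With the pooled list 32 of 36 epithelium genes were marked (exact adjusted p = 0.000378), 10 more than in the replicated list: the keratins Krt15, Krt8 and Krt18, the transcription factors Grhl1 and Ovol1, the desmosomal genes Dsc3 and Dsg3, and Sfn, Rab25 and Itgb4. Skeletal muscle stood at 28 of 34 (exact adjusted p = 0.0102) with Acta1, Actc1, Tnnc2, Neb, Chrng and Mymx, and cartilage at 19 of 23 (exact adjusted p = 0.0327, range over the alternatives 0.0327 to 0.87) with Acan, Matn1, Snorc, Cytl1 and Epyc. Neurons gained 7, Nefm, Rbfox3, Neurog1, Neurog2, Ascl1, Gad1 and Gad2, and stood at 16 of 26 (exact adjusted p = 0.917). Other genes named above as unmarked also had a pooled promoter peak: Grem1, Ibsp, Dmp1, Flt1, Sox17, Csf1r, Gata6, Nanog, Pax1, Dlx3, Tbx22, Foxe1 and Hoxa1. The 57917 peaks of the pooled list outside the replicated list had a median fold of 2.95, 14.9% of them lay at promoters, and 1196 coding genes were marked by them alone.

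The promoter peaks of several lists were wide for their strength. The median promoter peak of the facial mesenchyme list spanned 3868.5 bp, against 1345 bp in random lists of like fold (percentile 100). The medians were 3182 bp for bone, 2476 bp for tooth, 2060 bp for cartilage, 3026 bp for signalling and 3013 bp for cleft genes, each at percentile 100 of random lists of like fold. Olfactory genes stood at 1216 bp (percentile 98.6) and posterior limb and trunk regulators, with 5 promoters, at 1078 bp against 550 bp (percentile 98.0). Epithelium stood at 803 bp (percentile 97.6), skeletal muscle at 614.5 bp (percentile 84.4) and neurons at 532 bp (percentile 64.7). Housekeeping promoters, whose median fold of 17.5 equalled that of signalling genes, had a median width of 1795.5 bp (percentile 88.8).

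Some promoters had a peak in 1 replicate alone, and the balance between the replicates was tested for neurons alone. The 7 neuron genes marked in replicate 1 alone were Elavl3, Stmn2, Nefl, Rbfox3, Slc17a6, Gad1 and Gad2, and no neuron gene was marked in replicate 2 alone. The same holds for Hoxa1, Hoxa4 and Hoxa5 in HoxA. In muscle Myf6, Myl1, Neb, Chrng, Mymx and Ryr1 were marked in replicate 1 alone and Actc1 in replicate 2 alone. In epithelium Krt15, Krt18 and Cdh1 were marked in replicate 1 alone and Grhl1, Irf6, Ovol1, Dsg3, Pkp1 and Rab25 in replicate 2 alone. The facial mesenchyme genes Dlx3 and Tbx22 were marked in replicate 2 alone. Over all protein-coding genes 1140 were marked in replicate 1 alone and 479 in replicate 2 alone.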
